A study of Mus musculus with 6 samples.

How the data were processed

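Poly(A)-site tags from C57BL/6J mouse retina were measured at 6 stages, E13.5, E15.5, E18.5, P0, P6 and P21, with 1 sample per stage. Per the file headers, the deposited table gave counts of tags for each poly(A) site cluster in 12 columns, 2 for each stage, and 1 enrichment score per site over the whole series. Per the submitters' processing notes, reads were aligned with BWA 0.7.5a-r405 to mm10. How sites were clustered and filtered, how the score was computed, whether duplicate reads were removed and what the first and the second column of a stage stand for were not stated. All values in the count columns were whole numbers, the lowest score was 3.00 and the lowest total of a site was 41 tags. The first and the second column of a stage were added, since 1 sample was labelled per stage, and the columns were not treated as replicates in any test.

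The 32688 sites were placed on GENCODE M21 gene models (GRCm38) by the 3′ edge of each site. Read as 1-based, this edge lay most often exactly on annotated transcript ends on both strands. A site was given to a gene on the same strand if it lay in the gene or within 1000 bases downstream of it. Of the sites, 29105 were given to a gene and 182 lay in more than 1 coding gene. Tags outside genes and their flanks, and mitochondrial tags, were counted separately. The share of tags given to a gene ran from 97.5% at E13.5 to 95.5% at P21. CPM values of genes were scaled with TMM library sizes. The floor of 3 tags corresponded to 0.644 to 0.913 CPM over all tags of a library. PCR reads are not independent molecules, so intervals and floors cover counting error only.

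Abundance was tested on tags summed per gene with edgeR 4.0.16 in R 4.3.3 (TMM, quasi-likelihood F test). Genes needed a CPM of at least 1 in at least 2 libraries. The model had 1 linear term, stage order from 1 (E13.5) to 6 (P21), which left 4 residual degrees of freedom, so departures from a straight line counted as spread. Fitted changes are log2 changes over the 5 steps from E13.5 to P21 at the default prior count of edgeR. Their standard error (SE) was taken as the absolute change divided by the square root of the F statistic. A prior count of 2 was used only for the log2 CPM values of the list tests. Benjamini-Hochberg adjusted p values of 0.05 or less were called. Where a library held no tags of a gene, the fitted change depends on the prior count and is no bound, so list medians were also taken from observed P21 to E13.5 ratios with counts under 3 in a library set to 3.

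There were 23 gene lists, fixed before the data were examined, for the cell classes of the retina, the cell cycle, synapses, RNA processing, oxidative phosphorylation, ribosomes and other cells that a dissection could hold. They were tested with camera from limma 3.58.1 with a preset inter-gene correlation of 0.01 and with an estimated one, and with fry. Calls per gene were also made with p values adjusted over the list alone.

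Site choice was tested with diffSpliceDGE of edgeR. For each gene the pair of sites with the most tags was taken, each with at least 5% of the gene's tags and with a mean of at least 20 tags per library at the pair. The 3′-most site was called distal and the other proximal. The distal share is the percentage of the tags at the pair that fell on the distal site, with 95% Wilson intervals for single genes. The median distal share over genes and the shares of tags in 7 kinds of location were compared with stage order by two-sided exact permutation tests of Spearman's rho and Pearson's r over all 720 orders, in which the smallest possible p is 0.00278. Gene-bootstrap intervals (1000 draws) cover the choice of genes, not the spread between retinas. Pairs of stages were compared by counts without a test, using a 2-fold change with at least 20 tags in the larger library, or a move of 20 percentage points with at least 20 tags at the pair in both libraries.

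Poly(A) signals were searched in annotated transcript sequence in the 40 bases before a site, and A-rich sequence (6 A in a row, or 7 A among 10 bases) in the 20 bases after it. The last 75 bases of transcripts at abundant sites were aligned to all other annotated transcripts with BLAST 2.17.0, at 90% identity or more over 60 bases or more. Genomic sequence was not searched.

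Named genes followed a rule fixed before the data were examined. For abundance these were the 8 rising and the 8 falling genes with the largest fitted change among those past the threshold with a mean CPM of at least 20 and at least 4 of the 5 steps in 1 direction, and up to 3 members per list with the largest change past the threshold, filled by the members of highest mean CPM. For site choice these were the 8 distal-shifting and the 8 proximal-shifting genes with the largest difference in share between the last and the first stages and at least 20 tags in each library, and up to 6 members of the lists. A few genes that the rule picked are not reported here.

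Alternatives fixed before the data were examined were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter, a CPM of at least 5, days after conception with birth taken as day 19, each library left out in turn, limma voom with diffSplice, quasi-binomial regression (glm in R), site shares of at least 10%, a mean of at least 100 tags, the 3′-most site against all others, pairs within the 3′ UTR, a tag-weighted mean, thinning to the smallest library, shares of sites in place of tags, and thresholds of 4-fold and 30 percentage points. The first and the second columns alone were added after seeing the data. Median-of-ratios size factors moved the median change of all genes by 0.0449 on the log2 scale relative to TMM. The trend tests were also tested on simulated data with 200 changed genes and a dispersion set from the real libraries. For abundance, 74% of log2 changes of 2 and 100% of changes of 4 were found, with 7 false calls. For site choice, 28% and 97% were found, with 16 false calls. SciPy 1.17.1, NumPy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 in Python 3.11.15 were used for the other steps.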

Results

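The sequencing libraries counted the 3′ ends of polyadenylated RNA in the developing mouse retina, from E13.5, when progenitors still divide, to P21, when the retina holds differentiated neurons. Each of the 6 stages had 1 sample, so no value has a replicate, and every test between stages asked whether a measure followed stage order over the 6 libraries. The libraries held 3813236 tags at E13.5, 3861855 at E15.5, 4656153 at E18.5, 3286158 at P0, 4109941 at P6 and 3924759 at P21. The strongest nuclear site took 0.0973% to 0.216% of the tags of a library. Tags fell on 32688 sites, and 14474 nuclear genes had at least 1 site. The series concerns alternative polyadenylation during retinal development, so abundance of transcripts and choice between their 3′ ends were both followed.

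The fixed lists of the cell cycle and of retinal progenitors fell and those of photoreceptors, bipolar cells and synapses rose with stage, each with a preset correlation and none with an estimated one (adjusted p = 0.230 or more). By fry each of these lists passed (adjusted p = 0.0372 or less). Of 14469 genes tested, 2458 rose and 1897 fell with stage order. Among the genes with the largest rise, Fbxo2, which encodes a neuronal F-box protein, went from 0.274 CPM (1 tag) to 125 CPM (fitted log2 change 8.78 ± 1.08, SE, 6 libraries), and Grm6, the glutamate receptor of ON bipolar cells, from 6.30 to 270 CPM (5.96 ± 1.16). Pla2r1, a phospholipase A2 receptor, went from 0.274 CPM (1 tag) to 105 CPM (6.51 ± 1.11), and Fam19a3, a secreted brain protein, from 1.10 to 64.7 CPM (6.06 ± 0.54). The noncoding or unnamed genes Gm44196, Uckl1os and Gm47543 rose by fitted log2 changes of 6.85, 5.88 and 5.74. Among the genes with the largest fall, Sfrp2, a secreted modulator of Wnt signalling, went from 704 to 17.8 CPM (-5.38 ± 0.58), Hmga2, a chromatin protein of embryonic cells, from 71.5 to 1.92 CPM (-4.66 ± 0.48), and Wdr86, Inava and Gm266 had fitted changes of -5.42, -4.67 and -4.66. The embryonic globins Hba-x and Hbb-y also fell, with changes of -6.31 and -4.86. Their sequences resemble other globins, so their tags are less certain.

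The edgeR counts at an unadjusted p under 0.05 were 3359 rising and 3003 falling genes. Counts rested on single libraries. Without E13.5, 1254 genes rose and 728 fell, without P21, 873 and 421, and falling genes numbered 789 without E15.5 and 995 without P6. The calls of Pla2r1 and Gm47543 were lost without P21, and that of Hbb-y without E13.5. The median log2 ratio of the first to the second column was 2.01 for 117 late-specific genes at E13.5 and 3.49 for 27 early-specific genes at P21, so low levels depend on the column. Sfrp2 at P21 stood at 35.6 CPM in the first column and had 0 tags in the second.

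**Figure D1:**
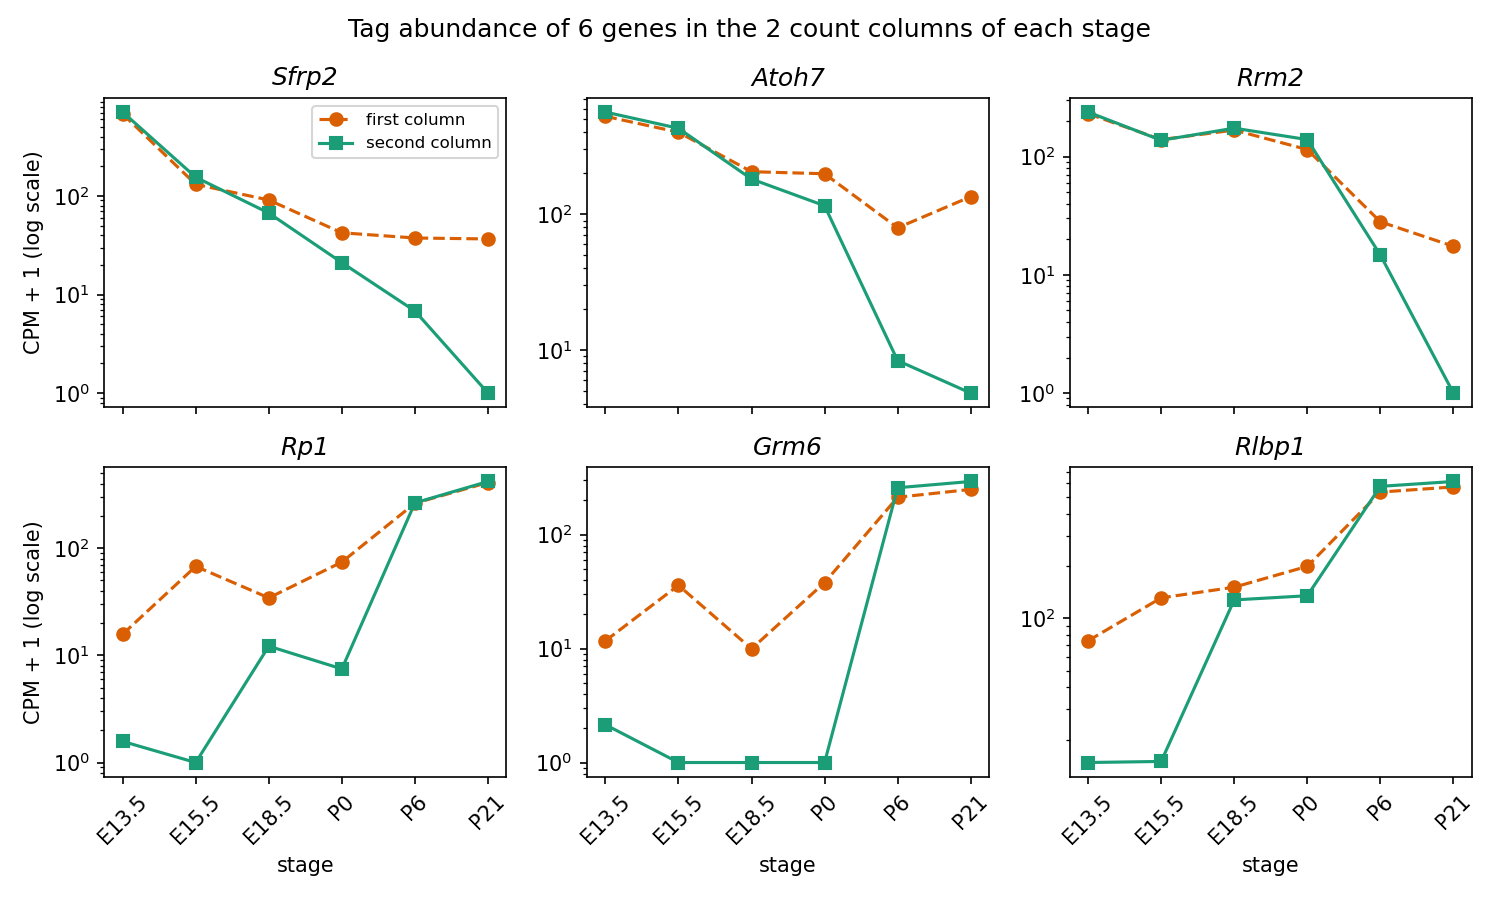
CPM plus 1 on a log scale against stage for Sfrp2, Atoh7, Rrm2, Rp1, Grm6 and Rlbp1, with the first and the second column of each stage as separate lines. Sfrp2 and Atoh7 fell and Rp1, Grm6 and Rlbp1 rose in both columns, Rrm2 fell in the sum and the first column but did not pass in the second, and Rp1 at E13.5 stood at 14.8 CPM in the first and 0.574 in the second column.

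Cell division genes fell. Of the 30 measured genes of the cell cycle and DNA replication list, 22 fell, 0 rose and 8 did not pass (28 fell when adjusted over the list alone, and 9 in the second columns over all genes), with a median fitted log2 change of -3.09 (camera, adjusted p = 4.29e-12; adjusted p = 0.363 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, went from 237 to 8.22 CPM (-4.29 ± 1.04), Bub1, a spindle checkpoint kinase, from 58.6 to 3.56 CPM (-4.003 ± 1.005), and Ube2c, a mitotic ubiquitin-conjugating enzyme, from 220 to 15.3 CPM (-3.90 ± 0.81). Of 25 retinal progenitor genes, 15 fell and 10 did not pass (15 fell when adjusted over the list alone), with a median of -1.70 (adjusted p = 9.65e-09; adjusted p = 0.242 with an estimated correlation). Examples were Sfrp2, Fgf15, a secreted growth factor of progenitors, from 487 to 57.3 CPM (-3.46 ± 0.64), and Atoh7, the transcription factor that makes progenitors competent to form ganglion cells, from 552 to 68.8 CPM (-3.45 ± 0.45). Without P21 the calls of Rrm2, Bub1, Ube2c and Fgf15 were lost, and without P6 and in the second columns alone those of Rrm2 and Bub1. At P21 the first and the second column gave 113 and 1.10 CPM for Fgf15 and 134 and 3.84 CPM for Atoh7. The observed median ratio of P21 to E13.5 in the cell cycle list, on the log2 scale with counts under 3 in a library set to 3, was -2.27 in the first columns and -4.86 in the second.

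Photoreceptor genes rose. Of 29 rod and phototransduction genes, 25 rose and 4 did not pass (27 rose when adjusted over the list alone), with a median change of 3.85 (adjusted p = 4.29e-12; adjusted p = 0.299 with an estimated correlation). Rp1, a protein of the outer segment axoneme, went from 8.22 to 414 CPM (5.41 ± 0.73), Gucy2e, a retinal guanylate cyclase, from 6.85 to 316 CPM (4.91 ± 0.78) and Gngt1, the gamma subunit of rod transducin, from 13.4 to 390 CPM (4.79 ± 0.77). Of 15 cone genes, 9 rose and 6 did not pass (12 rose when adjusted over the list alone), with a median of 3.51 (adjusted p = 9.83e-07; adjusted p = 0.230 with an estimated correlation). Arr3, cone arrestin, went from 4.93 to 257 CPM (5.06 ± 0.95), Kcne2, a potassium channel subunit, from 1.92 to 141 CPM (5.42 ± 0.87), and Opn1mw, the middle-wavelength cone opsin, from 4.66 CPM at E13.5 to 29.6 at P0, 11.8 at P6 and 298 at P21 (4.64 ± 1.25). The second columns held 0 tags of Opn1mw at the 4 stages up to P0, so its levels there and the step from P0 to P6 come from the first columns alone. Of 19 photoreceptor differentiation genes, 15 rose and 4 did not pass (16 rose when adjusted over the list alone), with a median of 3.10 (adjusted p = 1.74e-08; adjusted p = 0.242 with an estimated correlation). Impg1, an interphotoreceptor matrix proteoglycan, had a change of 5.63 ± 1.12, and Fscn2, a photoreceptor actin-bundling protein, of 4.91 ± 0.91. The calls of Kcne2, Arr3, Opn1mw, Impg1 and Fscn2 were lost without P21, and that of Opn1mw also without E13.5, without E18.5 and in the first columns alone. On the log2 scale, the observed median P21 to E13.5 ratio was 3.46 in the first columns and 6.85 in the second for the rod list, 3.23 and 5.40 for the cone list, and 2.45 and 4.51 for the photoreceptor differentiation list.

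Genes of inner retinal neurons moved in both directions. Of 20 retinal ganglion cell genes, 10 fell, 2 rose and 8 did not pass (11 and 2 when adjusted over the list alone), with a median of -0.97 (adjusted p = 0.00101; adjusted p = 0.230 with an estimated correlation). Sox11, a transcription factor of young neurons, fell from 661 to 65.2 CPM (-3.41 ± 0.52), while Nefh, the heavy neurofilament protein, rose from 10.4 to 257 CPM (4.03 ± 0.57) and Thy1, a neuronal surface glycoprotein, from 9.86 to 217 CPM (3.80 ± 0.67). Of 19 amacrine cell genes, 9 rose, 1 fell and 9 did not pass (9 and 1 when adjusted over the list alone), with a median of 1.52 (adjusted p = 0.00332; adjusted p = 0.299 with an estimated correlation, and 0.0846 with days after conception). Gad1, a GABA-synthesising enzyme, went from 3.56 to 153 CPM (4.73 ± 0.41), Neurod2, a neuronal transcription factor, from 1.92 to 57.0 CPM (5.01 ± 0.67) and Chat, the acetylcholine-synthesising enzyme, from 0.548 CPM (2 tags) to 10.96 CPM (4.52 ± 0.91). Of 19 bipolar cell genes, 14 rose and 5 did not pass (15 rose and 1 fell when adjusted over the list alone), with a median of 3.87 (adjusted p = 2.19e-05; adjusted p = 0.332 with an estimated correlation). Sebox, a homeobox protein with 1 tag at E13.5, had a change of 6.53 ± 1.19, and Scgn, a calcium-binding protein, of 5.58 ± 0.89. The observed median P21 to E13.5 ratio of the bipolar list was 3.19 in the first columns and 4.73 in the second on the log2 scale. Of 8 horizontal cell genes, 4 rose and 1 fell (4 and 1 when adjusted over the list alone), and the list did not pass (median 1.51, adjusted p = 0.0991; adjusted p = 0.483 with an estimated correlation). The horizontal cell list came out at adjusted p = 0.0495 without E15.5 and 0.0287 without P21. Calb1, a calcium-binding protein, rose from 6.30 to 214 CPM (4.60 ± 0.60), Sept4, a septin, by 1.80, and Onecut2, a transcription factor of horizontal cell genesis, fell from 76.1 to 12.1 CPM (-2.52 ± 0.29). Chat and Sebox lost their calls without P21, Thy1 and Neurod2 with days after conception.

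Of 20 Müller glia genes, 8 rose, 1 fell and 11 did not pass (9 and 1 when adjusted over the list alone), with a median of 0.93 (adjusted p = 0.0165; adjusted p = 0.230 with an estimated correlation). Rlbp1, a retinaldehyde-binding protein, went from 46.0 to 592 CPM (3.98 ± 0.36), and Slc14a1, a urea transporter with 2 tags at E13.5, and Abca8a, a lipid transporter, had changes of 5.28 ± 0.77 and 4.65 ± 1.13. The call of Abca8a was lost without P21 and without E13.5. The second columns held 0 tags of Abca8a at every stage up to P0, so its levels there come from the first columns alone. Of 30 genes of synapses and neurotransmitter release, 25 rose and 5 did not pass (26 rose when adjusted over the list alone), with a median of 2.09 (adjusted p = 1.03e-13; adjusted p = 0.230 with an estimated correlation). Cacna1f, the photoreceptor calcium channel, went from 9.86 to 370 CPM (4.81 ± 0.68), Cplx4, a complexin of ribbon synapses, from 4.66 to 242 CPM (5.06 ± 0.85, lost without P21) and Lrit1, a photoreceptor synaptic protein, from 9.59 to 296 CPM (4.79 ± 0.67).

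**Figure D2:**
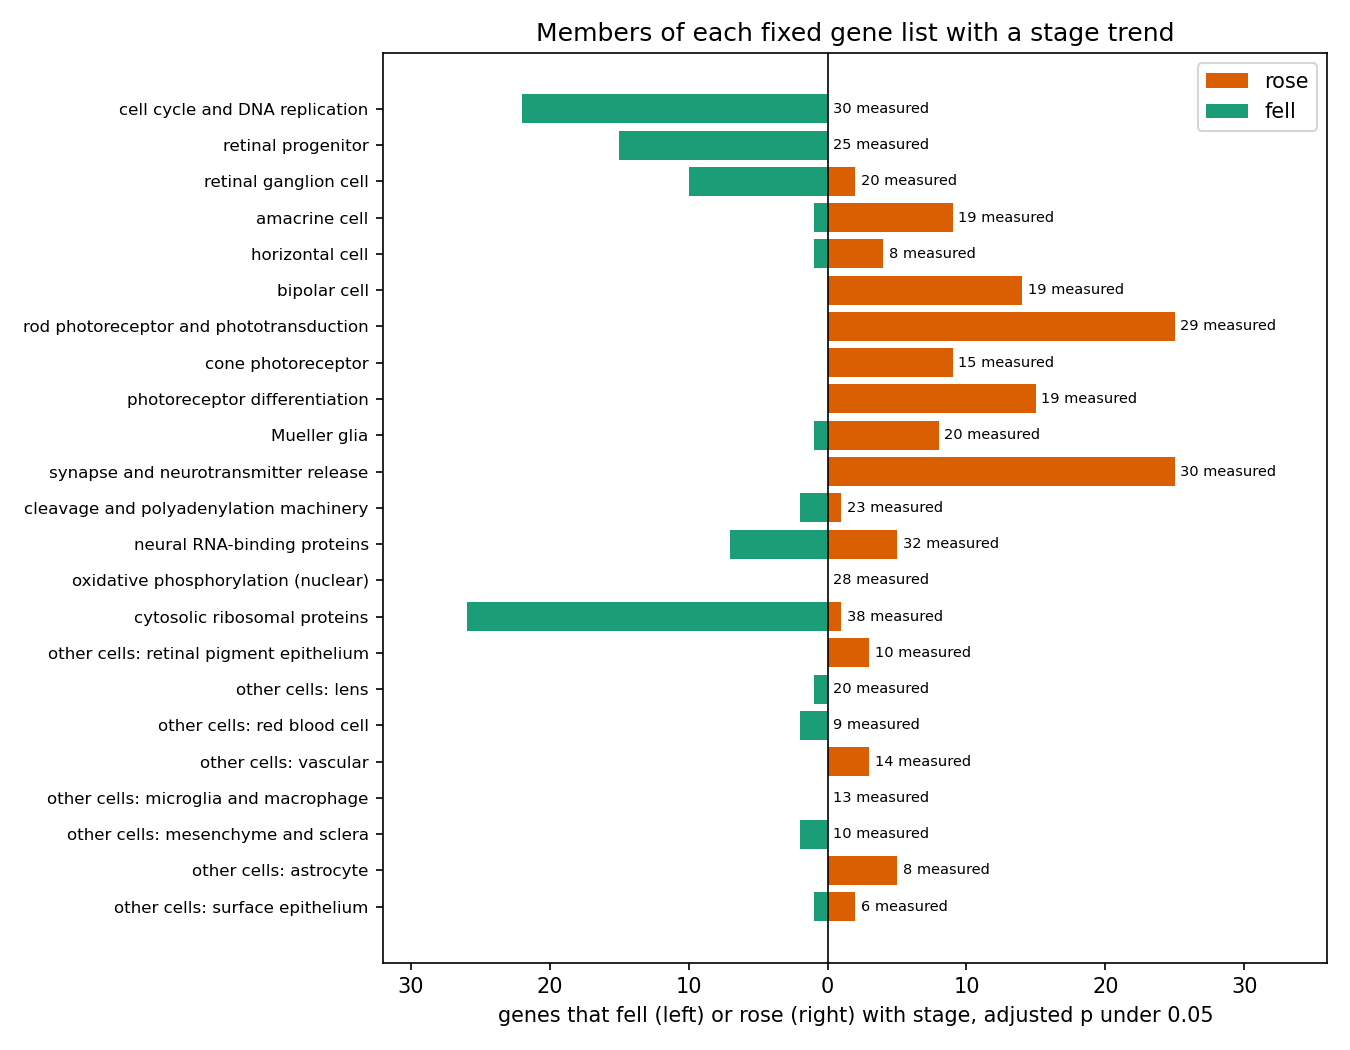
Number of measured members of each fixed gene list that rose or fell with stage order at an adjusted p of 0.05 or less (edgeR, 6 libraries, 1 per stage). The bars for rods and for synapses each reach 25 rising genes, and those for the cell cycle and for ribosomal proteins reach 22 and 26 falling genes.

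Cytosolic ribosomal protein genes fell. Of 38 measured, 26 fell, 1 rose and 11 did not pass (29 and 1 when adjusted over the list alone), with a median of -1.12 (adjusted p = 1.81e-09; adjusted p = 0.230 with an estimated correlation). Rps6 went from 87.6 to 14.0 CPM (-2.85 ± 0.43) and Rps4x from 6.57 to 1.10 CPM (-2.69 ± 0.67), while Rpl13 rose from 3.01 to 45.5 CPM (5.13 ± 1.23). These genes have many processed pseudogenes, so shared reads make single members less certain, and the calls of Rps4x and Rpl13 were lost without P21 and without E15.5, and that of Rps4x also without E13.5, without P6 and in the first columns alone. None of 28 nuclear oxidative phosphorylation genes passed in edgeR (median -0.08, adjusted p = 0.377; adjusted p = 0.752 with an estimated correlation). Atp5a1, Atp5b and Cox4i1, subunits of ATP synthase and of cytochrome oxidase, had changes of -0.22, -0.05 and -0.12.

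The RNA processing lists did not pass as groups. Of 23 genes of the cleavage and polyadenylation machinery, 1 rose, 2 fell and 20 did not pass (0 and 2 when adjusted over the list alone), with a median of -0.25 (adjusted p = 0.129; adjusted p = 0.483 with an estimated correlation). Pcf11, a cleavage factor subunit, went from 55.6 to 102 CPM (0.81 ± 0.24), Ppp1ca, a phosphatase catalytic subunit, from 382 to 214 CPM (-0.72 ± 0.17) and Cpsf3, the endonuclease that cleaves RNA at the poly(A) site, from 151 to 98.4 CPM (-0.62 ± 0.15). Of 32 neural RNA-binding proteins, 5 rose, 7 fell and 20 did not pass (5 and 7 when adjusted over the list alone, 3 and 5 in the second columns over all genes), with a median of -0.09 (adjusted p = 0.603; adjusted p = 0.644 with an estimated correlation). The splicing regulators Rbfox1 and Mbnl1 had changes of 2.28 ± 0.44 and 2.14 ± 0.44, and Cpeb1, a regulator of cytoplasmic polyadenylation, of 2.15 ± 0.68. Each of these 6 calls was lost without P21, and all but that of Mbnl1 also without E13.5. Those of Pcf11, Ppp1ca, Cpsf3 and Cpeb1 were lost without E15.5 as well, those of Pcf11, Ppp1ca and Cpsf3 without P6, those of Pcf11 and Cpeb1 without E18.5, and that of Cpeb1 without P0 and in either column alone.

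Lists of other cells that a dissection could hold moved less evenly. Of 8 astrocyte genes, 5 rose and 3 did not pass (7 rose when adjusted over the list alone; median 3.45, adjusted p = 2.17e-04; adjusted p = 0.230 with an estimated correlation). Gfap, an intermediate filament protein, went from 0.548 CPM (2 tags) to 35.1 CPM, S100b, a calcium-binding protein, from 0.822 to 32.3 CPM and Slc1a2, a glutamate transporter, from 26.0 to 272 CPM. Of 14 vascular genes, 3 rose (3 when adjusted over the list alone; median 1.19, adjusted p = 0.0257; adjusted p = 0.483 with an estimated correlation, and 0.248 without P21). By fry the vascular list did not pass (adjusted p = 0.172). Rgs5, a pericyte gene, went from 6.85 to 104 CPM, Tek, an endothelial receptor, from 1.10 to 18.1 CPM and Flt1, a receptor for vascular growth factor, from 5.20 to 46.6 CPM. Of 10 pigment epithelium genes, 3 rose (3 when adjusted over the list alone; median 0.60, adjusted p = 0.162; adjusted p = 0.644 with an estimated correlation). Rgr, a retinal opsin, went from 3.29 to 107 CPM, Ttr, a thyroxine and retinol carrier, from 6.03 to 158 CPM and Rdh5, a retinol dehydrogenase, from 5.48 to 42.8 CPM. The calls of Tek, Flt1, Rgr, Ttr and Rdh5 were lost without P21, those of Tek and Flt1 without E13.5, and that of Flt1 also without E18.5, without P6 and in the first columns.

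Of 9 red blood cell genes, 2 fell (2 when adjusted over the list alone; median -0.73, adjusted p = 0.0991; adjusted p = 0.640 with an estimated correlation), the embryonic globins Hba-x and Hbb-y, while the adult globin Hbb-bs stood at 208 CPM at E13.5 and 209 at P21. Of 10 genes of mesenchyme and sclera, 2 fell (2 when adjusted over the list alone; median -1.28, adjusted p = 0.225; adjusted p = 0.481 with an estimated correlation), Col5a1, a fibrillar collagen, from 71.8 to 13.7 CPM and Fn1, fibronectin, from 102 to 35.6 CPM, and Sparc, a matrix glycoprotein, stood at 280 and 360 CPM. Of 20 lens genes, 1 fell (0 when adjusted over the list alone; median -0.88, adjusted p = 0.176; adjusted p = 0.752 with an estimated correlation). From E13.5 to P21 the crystallin Cryaa stood at 328, 590, 134, 372, 40.2 and 178 CPM, with 6 tags in the second column at P0 against 1177 in the first, and Cryba1 at 190, 518, 67.6, 589, 27.9 and 133 CPM. The lens genes summed to 3400.3 CPM in the first and 3759 in the second column at E15.5 and to 4995 and 4992 at P0, against 638 and 421 at E18.5 and 390.4 and 169 at P6, so the E15.5 and P0 libraries stood apart in both columns. The observed median P21 to E13.5 ratio of the lens list was 0.08 in the first columns and -0.73 in the second on the log2 scale. None of 13 microglia genes passed in edgeR (median -0.01, adjusted p = 0.673; adjusted p = 0.880 with an estimated correlation), with C1qb at 38.9 and 35.9 CPM, C1qa at 24.1 and 19.7 CPM and Ctss at 26.6 and 34.5 CPM at E13.5 and P21. Of 6 surface epithelium genes, 2 rose and 1 fell (2 and 1 when adjusted over the list alone; median 0.39, adjusted p = 0.673; adjusted p = 0.752 with an estimated correlation), namely Krt18 and Perp, a keratin and a desmosome protein, up to 73.2 and 15.3 CPM, and Epcam, an epithelial adhesion protein, down from 26.0 to 1.64 CPM. Epcam and Perp lost their calls without E13.5 or P21, and Krt18 without P21. As groups, the pigment epithelium list passed without E13.5 (adjusted p = 0.0209) and with days after conception (0.0316), the lens list without E13.5 (0.0268), the red blood cell list without E18.5 (0.0496) and without P21 (5.93e-04), and the mesenchyme list without P21 (0.0470).

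The interval from P0 to P6, when rod and bipolar cells differentiate, had the most changes in abundance between neighbouring stages. Between P0 and P6, 1354 genes were at least 2-fold higher and 936 at least 2-fold lower. Rp1 went from 39.96 to 261 CPM, Grm6 from 18.6 to 232 CPM and Rrm2 from 125 to 20.7 CPM. The levels at P0 depended on the column, with 73.2 CPM in the first and 6.47 in the second for Rp1, and 36.9 CPM and 0 tags for Grm6. From P6 to P21 there were 1198 higher and 709 lower genes (464 lower in the first columns alone), from E13.5 to E15.5, 749 and 359 (488 higher in the second columns alone), and from E15.5 to E18.5, 702 and 314. Between E18.5 and P0, the closest in age, there were 263 and 738. From E13.5 to P21, 3083 genes were higher and 2441 lower. Comparisons with E15.5 and P0 include their higher levels of lens genes, which summed to 4995 CPM at P0 and 638 CPM at E18.5 in the first columns. With 1 library per stage these counts have no replicate check and no p. Within 1 stage, 123 to 407 genes were 2-fold higher in the first column than in the second, and 10 to 42 the other way.

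Tags moved towards distal sites with stage. Over 6081 genes with a pair of sites, the median distal share was 57.8% at E13.5, 57.4% at E15.5, 59.4% at E18.5, 59.9% at P0, 60.7% at P6 and 61.9% at P21, a rise of 4.09 percentage points. Across the 6 libraries Spearman's rho with stage order was 0.943 (exact permutation p = 0.0167) and Pearson's r 0.960 (exact permutation p = 0.00833), and r was 0.9496 without E13.5 and P21. This was the only relation computed in its family, so its adjusted p equals the raw one. The value of rho was 0.9 (exact permutation p = 0.0833) without any 1 of E18.5, P0, P6 and P21. Within genes, 3742 had a higher and 2330 a lower distal share at P21 than at E13.5, with a median change of 2.48 points (gene-bootstrap 95% interval 2.27 to 2.78).

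**Figure D3:**
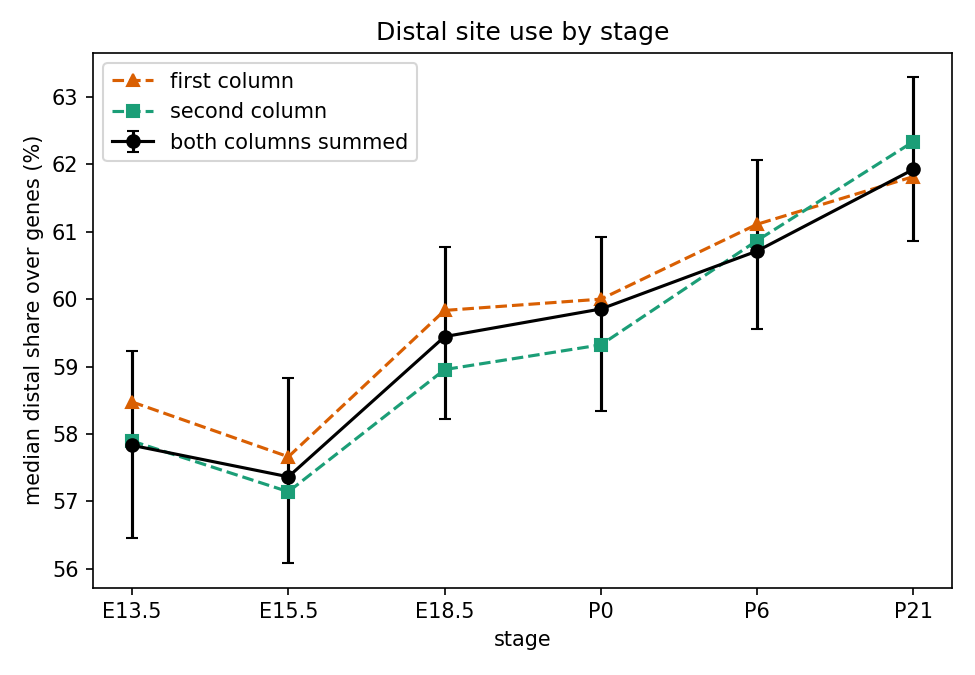
Median over 6081 genes of the percentage of tags on the distal site of a gene's pair, against stage, for the sum of the count columns with gene-bootstrap 95% intervals and for each column alone; the axis does not start at 0. The sum went from 57.8% to 61.9%, the first columns from 58.5% to 61.8% and the second from 57.9% to 62.3%.

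In single genes, 96 shifted to the distal and 32 to the proximal site. Ryr3, an intracellular calcium channel on chromosome 2, used a site in an intron (112714420) and a 3′ UTR site (112631377, mm10), and its distal share went from 5.43% at E13.5 (95% Wilson interval 2.65 to 10.8, 129 tags) to 82.6% at P21 (75.2 to 88.1, 132 tags). Its log2 ratio turned to -0.0932 in pairs within the 3′ UTR, which leave out the intron site. Mbd2, a methylated-DNA binding protein on chromosome 18, went from an intron site (70582914) to its 3′ UTR site (70626129), with 30.4% (26.6 to 34.5) at E13.5 and 91.9% (87.7 to 94.8) at P21. Longer 3′ UTR forms rose in Hcfc2, a chromatin cofactor gene, from 21.6% to 67.0%, in Cds2, a phospholipid synthesis enzyme, from 19.6% to 55.7%, and in Mphosph9, a centrosomal protein, from 37.5% on 24 tags to 94.9% on 293 tags. Rps15a, a ribosomal protein, went from 15.5% at E13.5 to 16.8% at E18.5, 58.4% at P0 and 71.0% at P21, with its distal site 4686 bases downstream. Usp29, a deubiquitinase, went from 23.9% to 83.5% between sites 197077 bases apart. Gtpbp3, a mitochondrial tRNA-modifying enzyme, went from 12.05% to 64.1% with a distal site beyond the annotated gene end, which another transcript could share. It stood at 19.4% at E18.5 and 60.6% at P0. Most of the shifts of Rps15a and Gtpbp3 thus fell between E18.5 and P0, the closest in age, and cannot be read as developmental change alone.

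Proximal shifts were seen in Tubb5, a beta tubulin, whose distal share was 86.8% at P0, 32.0% at P6 and 29.3% at P21 (27.6 to 31, 2740 tags) between sites 884 bases apart on chromosome 17 (35834805 and 35833921). Tubulin genes have close paralogs, so its tags are less certain. Tpm3, a tropomyosin, went from 81.7% to 28.8%, and Nsd2, a histone methyltransferase, from 57.3% to 20.8%. Acer2, a ceramidase, went from 96.6% to 31.1%, but its log2 ratio was 0.32, in the opposite direction, when the 3′-most site was set against all others. Intron sites gained in Mllt10, a chromatin reader, from a distal share of 52.1% to 6.80%, and in Ppp1r3f, a phosphatase regulator, from 97.6% to 60%. In Fgfr2, a growth factor receptor, the share went from 93.0% to 24.0% between a pair of intron sites of which at least 1 lies in more than 1 coding gene. In Junb, an AP-1 transcription factor, it went from 48.1% on 27 tags to 2.63%, with a distal site beyond the gene end.

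Among the fixed lists, 14 genes of the cleavage and polyadenylation machinery had a pair, and 1 of them, Sympk, which encodes the scaffold protein symplekin, shifted to the proximal site, with a distal share of 96.3% at E13.5 (94.5 to 97.46) and 61.5% at P21 (57.4 to 65.4). Of 22 neural RNA-binding proteins with a pair, 1 shifted, Tardbp, which encodes the RNA-binding protein TDP-43, from 37.6% (34.0 to 41.4) to 62.8% (58.9 to 66.5) distal. Of 12 bipolar cell genes, 1 shifted, Gnao1, a G protein subunit, from 60.3% to 91.8% and away from an intron site, with a log2 ratio of -0.41, in the opposite direction, in pairs within the 3′ UTR. Of 12 genes of the ribosomal protein list, which does not hold Rps15a, 1 shifted, Rpl4, from 8.95% to 3.19%, and of 5 horizontal cell genes, 1, Tpm3. None of the other 18 lists had a called pair. The median change in distal share from the early to the late stages ranged from -8.67 points in 4 astrocyte genes to 19.8 in 1 microglia gene. It was -6.42 in 6 cone, -4.31 in 14 rod and -2.45 in 13 photoreceptor differentiation genes, 3.51 in 13 progenitor, 3.81 in 7 amacrine, 4.67 in 14 ganglion cell and 5.16 in the 12 bipolar genes. The difference between lists was not tested. Early shares in lists of late genes may rest largely on the first columns. At E13.5 the median level over measured rod genes was 49.9 CPM in the first and 2.87 in the second column. It was 15.8 and 2.30 CPM for cone, 62.6 and 19.5 for photoreceptor differentiation and 14.3 and 5.17 for bipolar genes. The changes of these lists therefore cannot be read as developmental shifts.

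**Figure D4:**
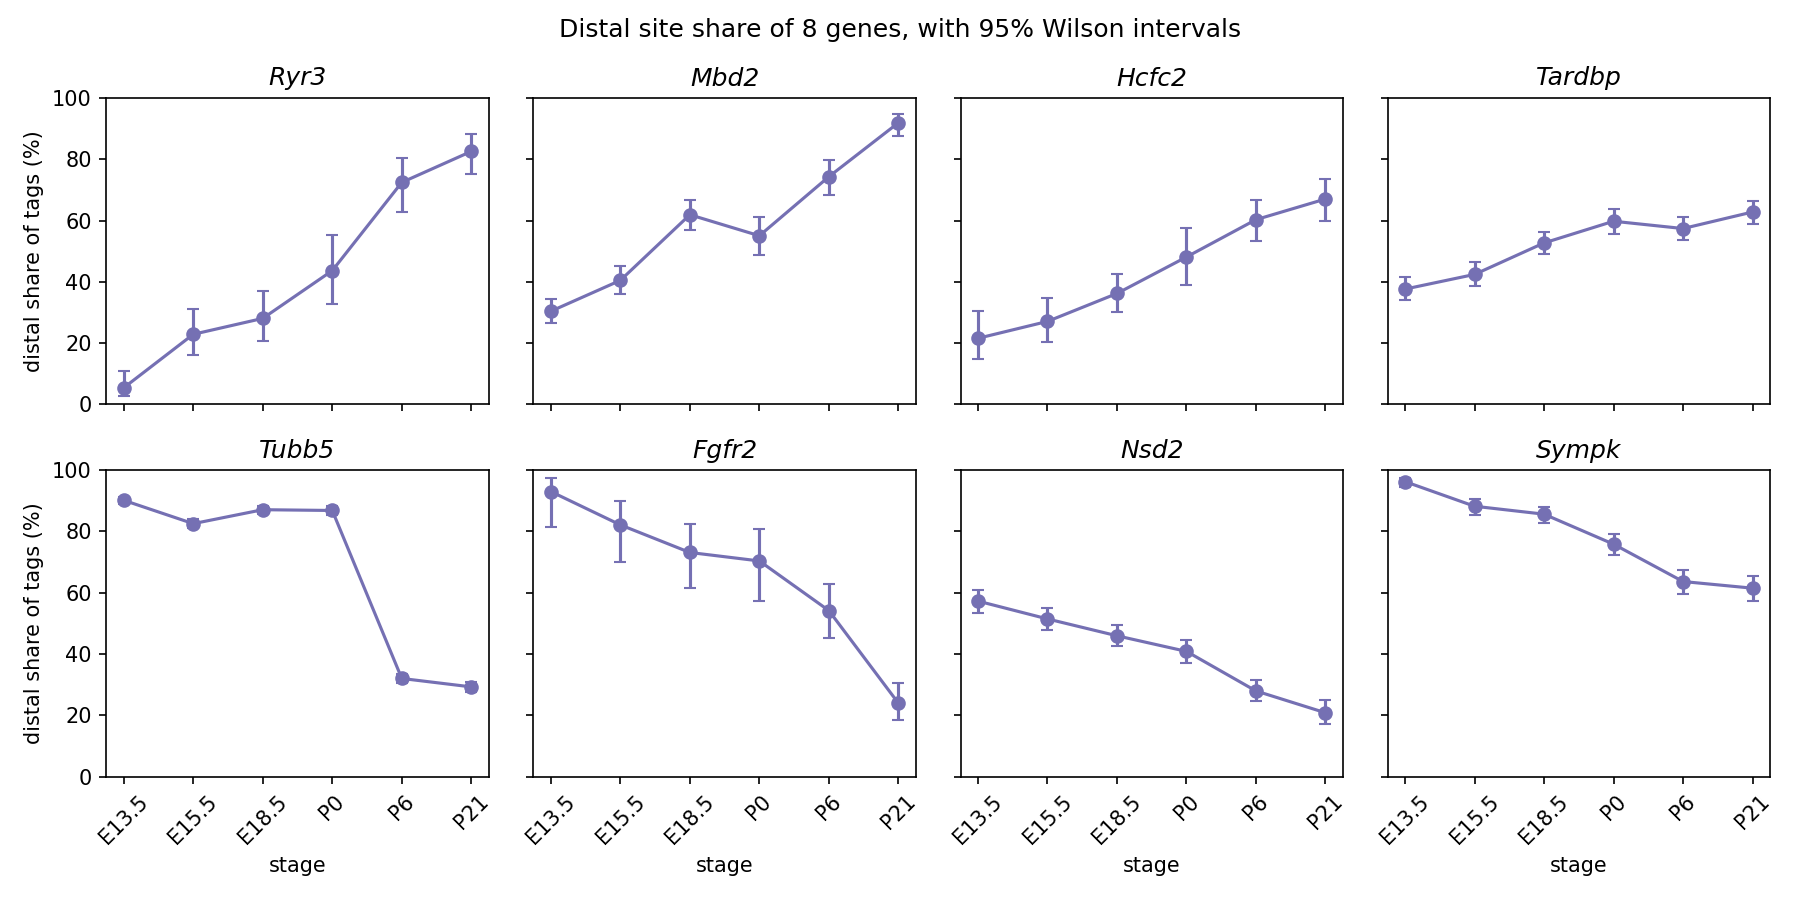
Percentage of tags on the distal site of the pair, with 95% Wilson intervals, against stage in Ryr3, Mbd2, Hcfc2, Tardbp, Tubb5, Fgfr2, Nsd2 and Sympk. The first 4 rose, Ryr3 from 5.43% to 82.6%, and the other 4 fell, Tubb5 mainly between P0 (86.8%) and P6 (32.0%).

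The site counts came from diffSpliceDGE of edgeR, with 717 distal and 230 proximal shifts at an unadjusted p under 0.05. In simulated data this test gave more false calls than its threshold allows. The site counts also rested on single libraries. Without E13.5 there were 0 and 0 (511 and 162 unadjusted), without P21, 4 and 0, without P6, 13 and 9, without E15.5, 18 and 7, and without E18.5, 38 and 12. Per-gene quasi-binomial regression, whose 4 residual degrees of freedom are not pooled over genes, gave 0 and 0 (770 and 276 unadjusted), and limma voom with diffSplice gave 69 and 18. Pairs within the 3′ UTR gave 54 and 10, and the first columns alone gave 37 and 13. Each of the 20 named shifts lost its call without E13.5, 18 without P21, 14 without P6, 12 without E15.5, 9 without E18.5, 11 with days after conception and 8 in the first columns alone. With days after conception, 36 of the 96 distal and 14 of the 32 proximal calls were shared.

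Sites outside annotated exons had no transcript sequence, which left 5393 proximal and 4781 distal sites of the 6081 pairs. The signal AATAAA stood before 51.7% of these proximal sites (95% Wilson interval 50.4 to 53.0) and 67.0% of these distal sites (65.7 to 68.4). The proximal and distal sets are thus not of the same pairs. In distal-shifting genes it stood before 60.9% (50.4 to 70.5) of 87 proximal and 85.3% (75.6 to 91.6) of 75 distal sites, and in proximal-shifting genes before 68.2% of 22 and 70.8% of 24. The sites of a pair lay a median of 972 bases apart in all genes, 3035 in distal-shifting and 9774.5 in proximal-shifting genes. Among neighbouring stages, moves of 20 points or more were distal and proximal in 75 and 129 genes from E13.5 to E15.5, 181 and 78 to E18.5, 147 and 209 to P0, 116 and 65 to P6, and 121 and 80 to P21 (53 proximal in the first columns alone). Among neighbouring stages, E18.5 and P0, the closest in age, had the most such moves, with more proximal than distal. The same held at 30 points and in each column alone. The number of moves thus did not follow the time between stages, so moves between neighbours cannot be read as developmental change alone. From E13.5 to P21, distal and proximal moves of 20 points or more were 393 and 150. These counts again have no replicate check and no p, and within 1 stage the second column was as much more distal than the first in 27 to 44 pairs and less distal in 31 to 53.

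The share of tags in annotated 3′ UTRs fell and the shares in introns and between genes rose. In 7 locations tested, with Benjamini-Hochberg adjusted values over the 7, 3′ UTRs held 86.0% of tags at E13.5 and 82.3% at P21 (rho -1, exact permutation p = 0.00278, the smallest possible, adjusted 0.00486; r -0.936, exact permutation p = 0.00278, adjusted 0.00486; r -0.970 without E13.5 and P21). Introns held 1.56% and 2.21% (rho 1, r 0.990, 0.990 without those stages), intergenic sequence 2.02% and 3.64% (rho 1, r 0.920, 0.984) and downstream flanks 7.49% and 7.98% (rho 1, r 0.949, 0.849), each with the same exact permutation p = 0.00278 and adjusted 0.00486 for rho and r. Noncoding exons held 1.24% and 1.69% (rho 0.943, exact permutation p = 0.0167, adjusted 0.0233; r 0.929, exact permutation p = 0.00556, adjusted 0.00778, 0.927 without those stages). Without any 1 of E13.5, E15.5, P6 and P21, rho for noncoding exons was 0.9, with adjusted exact permutation p from 0.0972 to 0.117. Coding and other exons went from 1.18% to 1.30% (rho 0.771, exact permutation p = 0.103, adjusted 0.120; r 0.816, exact permutation p = 0.0639, adjusted 0.0745, 0.603 without those stages). Mitochondrial tags were 0.499% and 0.898% (rho 0.600, exact permutation p = 0.242, adjusted 0.242; r 0.715, exact permutation p = 0.0806, adjusted 0.0806, 0.217 without those stages). By the share of sites in place of tags, the relation of downstream flanks turned to a rho of -0.543, and that of noncoding exons was 0.257 (exact permutation, adjusted p = 0.658). Coding and other exons turned to a rho of -0.943 (exact permutation, adjusted p = 0.0292), which passed in the opposite direction, and mitochondrial sites to -0.429.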

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

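No test in this part was chosen after its result was seen. Sites outside annotated genes and their flanks were left out of the gene comparisons and carried a signal of their own, tags that followed stage order. Of 3533 such sites tested with the stage-order trend of edgeR, 891 rose and 122 fell with stage. The site on chromosome 4 from 130530134 to 130530169 on the minus strand held 1220 tags at E13.5, 613 at P0 and 141 at P21, and that on chromosome 17 from 85062309 to 85062333 on the minus strand held 294, 327 and 680. No explanation was tested for these sites.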

How the results depend on the processing

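The settings with 1 column alone were chosen after the data were seen. Of 248 values of 38 results under other settings, 122 counts stayed within 1.5 times and 52 did not, while 62 correlations kept their direction and side of the threshold, 9 lost their call and 3 turned direction. With 1 library left out at a time, rising genes ranged from 873 to 2658, falling genes from 421 to 2406, distal shifts from 0 to 116, proximal shifts from 0 to 36, and rho from 0.9 to 1 for the median distal share and for noncoding exons. Fewer libraries leave fewer residual degrees of freedom. With an estimated correlation, 0 lists rose and 0 fell, against 9 and 4 with the preset one. By fry, 8 lists rose and 4 fell, and the vascular list did not pass. Distal and proximal shifts were 0 and 0 by quasi-binomial regression, 54 and 10 in pairs within the 3′ UTR, which tests fewer genes, and 37 and 13 in the first columns, and proximal shifts were 18 by limma voom. By the share of sites, rho was -0.543 for flanks, -0.943 for coding and other exons, -0.429 for mitochondrial sites and 0.257 for noncoding exons; the cause was not tested. Log2 site ratios turned to -0.0932 for Ryr3 and -0.41 for Gnao1 in pairs within the 3′ UTR, which leave out their intron sites, and to 0.32 for Acer2 with the 3′-most site against the rest.

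At 4-fold and 30 percentage points, which pass fewer genes by construction, higher, lower, distal and proximal genes were 145, 30, 17 and 28 from E13.5 to E15.5, 133, 71, 66 and 22 to E18.5, 53, 142, 42 and 75 to P0, 334, 345, 35 and 11 to P6, 382, 128, 17 and 12 to P21, and 1711, 881, 136 and 58 from E13.5 to P21. In the first columns, 464 genes were lower and 53 more proximal at P21 than at P6, and in the second columns 488 were higher at E15.5 than at E13.5; the cause was not tested. Of 80 genes picked by the naming rule for abundance, 0 turned direction in any setting, 33 lost their outcome without P21 and 14 without E13.5. No paired analysis was possible because each stage has 1 sample. At 3 tags, levels under 0.644 to 0.913 CPM could not be told from 0 by counting error alone. Higher summed levels are also uncertain where only the first column held tags. Opn1mw at E15.5 had 106 tags in the first and 0 in the second column, or 28.0 CPM in the sum. Gngt1 at E13.5 had 49 and 0 tags, or 13.4 CPM.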

Other observations

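Cytoskeletal genes, chosen after their values were seen, differed between the count columns. Tuba1a, an alpha tubulin of young neurons, had 1579 tags in the first and 33 in the second column at its main site at E13.5 and 963 and 768 at P21. Actb, cytoplasmic actin, had 2294 and 83 at E13.5 and 1684 and 1443 at P21. The break lay between P0 and P6. The Tuba1a site had 1233 and 9 tags at P0 and 1464 and 1314 at P6. The Actb site had 2178 and 82 at P0 and 2072 and 1926 at P6. The rise of the summed tags at these sites from P0 to P6 thus came mostly from the second columns.

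Tests of other-stage reads and of an age gap between retinas as explanations of the columns, and the second-column test of the distal share, were chosen after the result was seen. With the libraries put in 100 of their 360 distinct orders, the real one included, 1 order, the real one, gave as many genes with an abundance trend (4355, highest other 1450), and 1, again the real one, as many with a site trend (128, highest other 27). A chance order of the libraries is therefore argued against as the source of these counts. It is not excluded, since 100 of the 360 orders were drawn and all libraries are single.

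Late transcripts were seen in the first column of early stages. For 117 late-specific genes, picked by a 16-fold difference in the second columns of the other stages, the median log2 ratio of first to second column at E13.5 was 2.01, with 116 of 117 higher in the first. For 27 early-specific genes, picked from E13.5 and P6, it was 3.49 at P21, against 0.0204 in all 3436 genes of at least 100 CPM. An age gap between the retinas of the columns that runs the same way at every stage is argued against, since the first column held more late transcripts at E13.5 and more early ones at P21, while reads of the other stages' libraries may account for both, the smaller ratio being 2.01. A gap in either direction is also argued against at E15.5 and E18.5, where 179 and 172 of 238 late genes stood higher in the first column than in the second at P0, while early-specific genes lay above their P0 level by log2 medians of 0.79 and 0.32 (23 and 21 of 27 higher); at the other stages it stays open.

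Some abundant sites were nearly missing from the second column. There were 42, in 81 cases of a site at a stage, with at least 200 tags in the first column and 10 times fewer in the second. Such sites numbered 14 at E13.5, 25 at E15.5, 12 at E18.5, 17 at P0, 2 at P6 and 11 at P21. Summed counts at these sites therefore differ between stages partly through the second column. Of 38 searched, 5 matched a transcript of another gene (Actb, Eno1, Tmsb10, Rpl32 and Aldoa), against 51 of 3991 other abundant sites (Fisher's exact p = 1.53e-04), or 10.04 times the share expected after matching on abundance, so shared sequence may account for part of them, and 33 had no match in annotated transcripts. Other-stage reads as the only cause are argued against, since in 37.0% of cases (95% Wilson interval 27.3 to 47.9) the excess of the first column reached the highest second-column level at any other stage. The remaining sites stay open, and no biological explanation was tested.

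The rise of the median distal share was weighed against 3 explanations. Other-stage reads in the first column are argued against by a rise of 4.44 percentage points in the second column alone. Compressed counts of abundant sites are argued against by 2516 genes with stable totals, whose median change was 1.09 times that of all genes (2.70 points, gene-bootstrap 95% interval 2.36 to 3.01). A difference in depth is argued against by thinning every library to the smallest total, which left 0.969 of the rise. Developmental age, which the stages name, stays open as an untested explanation.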
